A study of Mus musculus with 30 samples.

How the data were processed

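The starting point was the table of gene counts deposited by the authors, 30538 genes in 30 libraries. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, aligned to GRCm38/mm10 with GSNAP and counted over genes with featureCounts of Subread 1.5.2, and edgeR 3.26.8 was used for testing. The libraries are polyA-selected and stranded. The strand setting of the counting and the annotation release are not stated, so counts of genes that overlap another gene on the opposite strand are uncertain, as are those of close paralogs such as Hspa1b and the Ifit and Gbp families. Gene symbols were matched to GENCODE vM21 for 30126 identifiers. No vehicle is named for the untreated groups, and it is not stated whether compounds stayed on during LPS.

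Counts were normalized with TMM and filtered with filterByExpr at a minimum count of 10, which kept 13173 genes. Of the rest, 11735 had no count in any library. The tested genes held at least 99.98% of the counts of every library. One edgeR quasi-likelihood fit held all 10 groups of 3 libraries, with 20 comparisons of group means, and p was adjusted by Benjamini-Hochberg over all tested genes. A gene is called at an adjusted p under 0.05. The tests, the 30 gene lists, the rule for genes named and the settings to vary were fixed before the data were examined. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

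Gene lists were tested with limma camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over 600 list and comparison pairs. Camera with the correlation estimated from the data, and fry, were run beside it. Of 216 camera calls, 1 stayed with the estimated correlation and 152 with fry. Adjusted over the list alone means that p was adjusted across a list's own members. Named genes are the 8 largest and 8 smallest fold changes of a comparison (5 and 5 for differences of responses and between compounds) with an adjusted p under 0.05, a log2 fold change of at least 1, an average log2 CPM of at least 2 and non-overlapping groups. Non-overlap of 3 and 3 libraries arises by chance in either direction in 10% of unchanged genes. Up to 4 members of each list with the smallest p and a fixed set of genes were added. Where a group had 0 counts, the fold is given as a lower bound from 3 reads over the group's summed libraries, and with 1 to 3 counts as a ratio with its counting interval.

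The mouse number was taken as the animal within a genotype. This was checked in the counts: after removal of group means, 24 of 24 wild-type and 6 of 6 Ch25h-/- libraries correlated best with libraries of their own number. The correlations were low, over 0.1 in 36 of 84 wild-type and 1 of 3 Ch25h-/- pairs of the same number (medians 0.0865 and 0.0906). The consensus correlation within animals was 0.0968. Every count is even in 20 libraries, while 9 (OSW-1 with LPS and all Ch25h-/- libraries) hold odd and even counts in equal shares (49.66 to 51.38% odd), and 1 (unstimulated 25HC, mouse 3) is mixed, with 46.13% odd. The even counts look like a doubling of reads, so reads of floors and intervals in those libraries were halved. All counts were used as given in the tests, and halving them was tried.

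The pipeline was tested on simulated data in which 200 genes were moved in counts drawn from the fitted model. At a 2-fold change it recovered 85.1% of the moved genes for unstimulated 25HC, 89.6% for OSW-1 with LPS, 83.6% for Ch25h-/- against wild-type and 79.1% for the 25HC response difference, and it called 9 of 12883, 10 of 12820, 3 of 12872 and 7 of 12878 unmoved genes. At a 1.5-fold change it recovered 65.7, 62.7, 61.2 and 22.4%. A list of 25 genes moved 1.5-fold was found in each of these 4 runs, and 1, 1, 0 and 2 of 100 unmoved lists had p under 0.05. Simulated genes varied independently of each other, so these runs do not give the false call rate for lists of correlated genes. Simulated libraries also held no animal effect, so recovery and false calls in the real libraries can be worse. A regrouping of the real unstimulated libraries of both genotypes called 186 genes, where the simulation called 3 unmoved ones.

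Settings varied by plan were DESeq2 size factors, no low-count filter, the mouse as a block, DESeq2, limma-voom with the animal as a random effect (duplicateCorrelation), a fit on the compared groups alone, and leaving out each library in turn. With the mouse number as a block, unstimulated Ch25h-/- against wild-type called 139 genes in place of 1. Mice are nested in genotype, so this block sets the genotypes against differences within animals and gives the call no support. With the number shared between genotypes 30 were called, and libraries of the same number in different genotypes correlated at a median of only 0.0219. The overlap of LPS calls between genotypes was counted only after the values were seen. Alternatives added after seeing the values were halved counts, Ch25h-/- libraries as controls for the compounds, and leaving out wild-type mouse 3. The proteins, lipids and cells of other experiments were not analysed here, nor were reads, splicing or sequence variants. A few genes are not reported here.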

Results

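Bone marrow derived macrophages from 3 wild-type mice and 3 mice without Ch25h, the enzyme that turns cholesterol into 25-hydroxycholesterol (25HC), were sequenced in 30 libraries. Wild-type cells were left untreated or pretreated for 18 h with 5 µM 25HC, 1 µM itraconazole (an azole antifungal) or 0.3 µM OSW-1 (a plant steroidal saponin), 3 compounds that the series groups as OSBP ligands. Each condition was harvested unstimulated or after 18 h with LPS at 10 ng/mL. Values with ± are log2 fold changes and standard errors from the edgeR fit, with 3 mice per group. Each standard error was derived as the size of the log2 fold change divided by the square root of its F statistic. For large changes from groups near 0 counts it is to be read as approximate. Levels are mean ± SD in CPM, counts scaled to library size. The standard errors rest on the spread within groups over all 30 libraries, moderated across genes, and not on the compared groups alone. Libraries of 1 mouse were taken as independent in them. The intervals and lower bounds given for genes with few reads carry counting error alone.

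Ch25h reads separated the genotypes. Untreated unstimulated wild-type libraries held 94, 86 and 46 Ch25h counts (2.22, 2.24 and 1.42 CPM) and Ch25h-/- libraries 7, 0 and 2 (0.277, 0 and 0.0768 CPM). The wild-type counts are the even ones that look doubled, so CPM and not counts compare the genotypes. With LPS the wild-type libraries held 40, 78 and 32 counts (1.23, 2.34 and 0.973 CPM) and the Ch25h-/- libraries 5, 3 and 0 (0.225, 0.127 and 0 CPM). Every compound raised Ch25h in unstimulated wild-type cells: 25HC by 2.35 ± 0.55 (10.1 ± 4.87 CPM, adjusted p = 0.0022), itraconazole by 2.78 ± 0.55 (13.6 ± 8.3 CPM, adjusted p = 0.000547) and OSW-1 by 3.44 ± 0.56 (21.5 ± 10.2 CPM, adjusted p = 3.01e-05). Among LPS-treated cells the Ch25h increase passed with itraconazole, at 1.82 ± 0.57 (adjusted p = 0.00924). The Ch25h change of untreated cells after 18 h of LPS did not pass (-0.38 ± 0.60, adjusted p = 0.599).

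LPS raised inflammatory and interferon-stimulated genes in untreated wild-type cells and lowered cell cycle genes. Saa3, an acute-phase apolipoprotein, rose by 13.49 ± 0.71 to 40600 ± 3880 CPM (adjusted p = 2.11e-14). The chemokine Ccl5 rose by 11.28 ± 0.30 to 6440 ± 905 CPM, the iron-siderophore binder Lcn2 by 11.55 ± 0.39, the cytokine Il1b by 10.04 ± 0.47 to 1570 ± 467 CPM, and Ptges, which makes prostaglandin E2, by 9.78 ± 0.39. Nos2, the inducible nitric oxide synthase, had no read in unstimulated cells and was at least 7980-fold higher with LPS. Hp (haptoglobin) rose by 11.58 ± 0.56, Il6 had a ratio of 110 (interval 30.1 to 918), and Il12b a ratio of 121 (41.1 to 591). Tnf was up by 2.23 ± 0.45 (adjusted p = 0.000139), Cxcl10 by 4.80 ± 0.52, Ccl2 by 2.90 ± 0.62 and the heme-degrading Hmox1 by 4.15 ± 0.33. Il10 did not pass the test. In all, 4056 genes were higher and 3968 lower of 13173 tested.

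The 34 interferon-stimulated genes tested were all higher with LPS (median 2.84, adjusted p = 1.7e-14, adjusted p = 0.5 with an estimated correlation; 34 adjusted over the list alone). Irf7, which amplifies interferon transcription, rose by 3.81 ± 0.27, the guanylate-binding Gbp2 by 4.09 ± 0.29 and the chemokine Cxcl9 by 8.40 ± 0.50. Of the inflammatory list, 20 of 24 members were higher and 4 neither (20 adjusted over the list alone; median 4.50, or 3.81 with members without reads set to their bounds; adjusted p = 4.9e-08, adjusted p = 0.5 with an estimated correlation). Negative regulators of Toll-like receptor signalling went the same way, 15 higher and 1 lower of 17 (adjusted p = 0.18 with an estimated correlation). Socs3 rose by 8.17 ± 0.30 and Socs1 by 4.06 ± 0.19, and Sigirr fell by 1.65 ± 0.29. Glycolysis genes were higher at 20 of 22 (median 1.68, adjusted p = 1.6e-09, adjusted p = 0.5 with an estimated correlation), led by Pfkfb3 (5.16 ± 0.19), the hexokinase Hk2 (2.97 ± 0.21) and the glucose carrier Slc2a1 (2.90 ± 0.23). Cell cycle genes were lower at 24 of 25 (median -4.06, adjusted p = 5.1e-18, adjusted p = 0.1 with an estimated correlation). The mitotic kinase Plk1 fell by 7.80 ± 0.21, Ccna2 by 8.45 ± 0.21, and Top2a by 5.17 ± 0.11, from 391 ± 30.9 to 10.8 ± 0.923 CPM. Cenpf, a kinetochore protein, had a ratio of 1590 (441 to 13200) in favour of unstimulated cells.

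Stress and secretory genes rose with LPS as well. The unfolded protein response list was higher at 17 of 20 members (median 0.77, adjusted p = 1.1e-05, adjusted p = 0.61 with an estimated correlation), with the chaperones Hyou1 at 1.64 ± 0.15 and Hspa5 at 0.99 ± 0.13. ATF4 targets of the integrated stress response were higher at 15 and lower at 2 of 23 (adjusted p = 0.012, adjusted p = 0.76 with an estimated correlation). Slc7a11, the cystine carrier, rose by 4.82 ± 0.50, and Psat1 fell by 1.51 ± 0.23. NRF2 targets were higher at 14 of 17, including the ferritin chain Fth1 (2.59 ± 0.13), with adjusted p = 0.61 with an estimated correlation. Antigen presentation genes were higher at 15 and lower at 2 of 19 (adjusted p = 7.5e-05, adjusted p = 0.5 with an estimated correlation). Golgi genes were higher at 15 of 20 (median 0.40, adjusted p = 0.00079, adjusted p = 0.61 with an estimated correlation), among them Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum (1.08 ± 0.09). The SREBP2 list of cholesterol genes split, 6 higher and 5 lower of 24 (median 0.09, adjusted p = 0.67, adjusted p = 0.98 with an estimated correlation). Hmgcs1 and Insig1 did not pass. The unstimulated cells were collected at time 0, so 18 h of culture goes with LPS in every one of these values. Mitochondrially encoded RNA was 1.63 ± 0.0662% of counts before and 1.06 ± 0.145% after LPS.

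In macrophages without Ch25h, LPS raised 3687 genes and lowered 3847. Of these, 3185 were higher and 3182 lower in wild-type cells too, where independent lists would share 1135 and 1159, and 4 were called in opposite directions. Saa3 rose by 15.45 ± 0.77, Ccl5 by 11.02 ± 0.30, Lcn2 by 10.56 ± 0.38, Il1b by 10.01 ± 0.48 (to 1630 ± 289 CPM), Irf7 by 4.39 ± 0.28 and Hk2 by 3.84 ± 0.22. Top2a fell by 5.32 ± 0.11 and the mannose receptor Mrc1 by 2.77 ± 0.27. Tnf rose by 1.16 ± 0.47 (adjusted p = 0.037) to 18.1 ± 2.58 CPM. The lists gave 34 of 34 interferon-stimulated genes higher (median 3.48, adjusted p = 0.48 with an estimated correlation), 18 of 24 inflammatory genes higher (median 3.87, or 3.69 with members without reads at their bounds, adjusted p = 0.5 with an estimated correlation), 21 of 22 glycolysis genes higher (median 2.03, adjusted p = 0.46 with an estimated correlation) and 24 of 25 cell cycle genes lower (median -3.64, adjusted p = 0.1 with an estimated correlation).

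**Figure D1:**
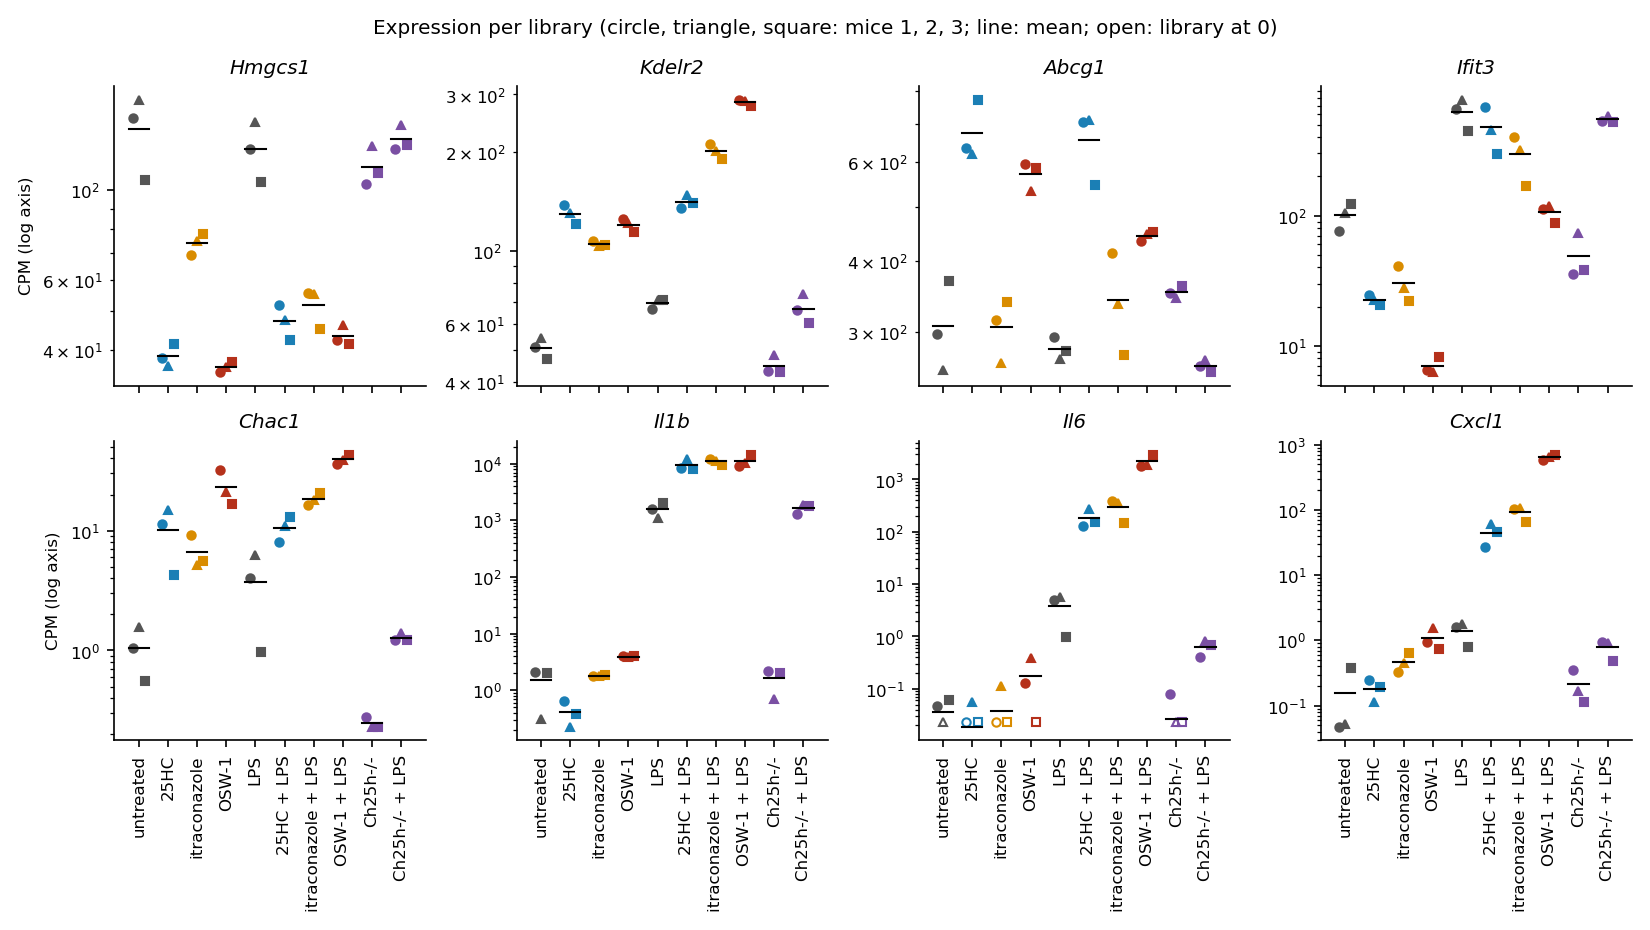
Levels of selected genes in each library of the 10 groups. Points are single mice.

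25HC lowered SREBP2 targets and interferon-stimulated genes in unstimulated macrophages and raised Golgi genes. Hmgcs1, an early enzyme of cholesterol synthesis, fell by 1.87 ± 0.14 (38.8 ± 2.57 against 142 ± 32 CPM, adjusted p = 8.63e-10) and Cyp51 by 2.38 ± 0.18 (17.6 ± 1.63 against 91.8 ± 27.4 CPM, adjusted p = 1.29e-09). Insig1, which retains SREBP in the endoplasmic reticulum, fell by 1.75 ± 0.15. The SREBP2 gene itself, Srebf2, fell by 1.24 ± 0.09. The cholesterol exporters Abcg1 and Abca1 rose by 1.13 ± 0.13 (676 ± 84.5 against 308 ± 57.1 CPM, adjusted p = 1.05e-06) and 0.93 ± 0.21 (adjusted p = 0.00169). Soat2, which esterifies cholesterol, rose by 3.38 ± 0.32. Of the SREBP2 list 23 of 24 members were lower (24 adjusted over the list alone; median -1.58, adjusted p = 5.5e-27, adjusted p = 0.18 with an estimated correlation). LXR targets were higher at 5 and lower at 1 of 14 (median 0.32, adjusted p = 0.18), with the ubiquitin ligase Mylip at 0.91 ± 0.14 and Srebf1 at 0.30 ± 0.10.

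Interferon-stimulated genes were lower with 25HC at 30 of 34 members (31 adjusted over the list alone; median -1.43, adjusted p = 2.3e-17, adjusted p = 0.5 with an estimated correlation). Oas2, an antiviral RNA sensor, fell by 1.48 ± 0.17 (49.7 ± 1.28 against 139 ± 11.3 CPM, adjusted p = 6.52e-07), the nucleic acid sensor Zbp1 by -1.93 ± 0.24, the GTPase Ifi47 by -1.43 ± 0.18 and Gbp7 by -2.47 ± 0.27. Golgi genes were higher at 17 of 20 (18 adjusted over the list alone; median 0.75, adjusted p = 3.4e-17, adjusted p = 0.16 with an estimated correlation). Kdelr2, the receptor that returns proteins to the endoplasmic reticulum, rose by 1.35 ± 0.08 (130 ± 8.88 against 50.9 ± 3.65 CPM, adjusted p = 1.93e-11), Sec24d by 1.31 ± 0.09 and the stacking protein Gorasp2 by 0.86 ± 0.07. The unfolded protein response list was higher at 19 of 20 (19 adjusted over the list alone; median 0.55, adjusted p = 4.2e-10, adjusted p = 0.5 with an estimated correlation), with Hyou1 at 1.17 ± 0.15 and Hspa5 at 0.87 ± 0.13. ATF4 targets were higher at 17 and lower at 1 of 23 (18 and 1 adjusted over the list alone; median 1.20, adjusted p = 9.2e-07, adjusted p = 0.5 with an estimated correlation). Chac1, which degrades glutathione, rose by 3.25 ± 0.47, the folate enzyme Mthfd2 by 1.97 ± 0.26, Atf4 by 1.27 ± 0.18 and Ddit3 by 1.10 ± 0.25. Ddit4 fell by 1.21 ± 0.17.

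Beyond these lists, 25HC raised the myeloid receptor Trem1 (5.46 ± 0.82), the secreted Olfml3 (3.96 ± 0.54), the fatty acid receptor Gpr84 (3.46 ± 0.45) and the Notch ligand Jag1 (3.17 ± 0.22). It lowered Ms4a4a (-4.12 ± 0.64), the transglutaminase F13a1 (-3.34 ± 0.54) and the carbonyl reductase Cbr2 (-3.27 ± 0.25). Inflammatory genes went both ways, 7 higher and 1 lower of 24 (median 0.38, adjusted p = 0.19). The neutrophil chemokine Cxcl2 rose by 2.68 ± 0.46, Tnf by 1.72 ± 0.44 and Ccl2 by 2.01 ± 0.60, while Il1b fell by 1.80 ± 0.53 (0.415 ± 0.209 against 1.49 ± 1.02 CPM, adjusted p = 0.0119). Antigen presentation genes were lower at 11 of 19 (median -0.50, adjusted p = 4.8e-05, adjusted p = 0.5 with an estimated correlation), with the class II transactivator Ciita at -2.98 ± 0.55. Osbp rose by 0.41 ± 0.09. In total 2098 genes were higher and 1686 lower, and the count was 2359 without mouse 2 of the 25HC group and 2462 without mouse 3 of the untreated group.

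Itraconazole shared the Golgi and interferon changes in unstimulated cells and moved cholesterol genes less, with no test passed for the exporters. Hmgcs1 fell by 0.94 ± 0.13 (74 ± 4.49 against 142 ± 32 CPM, adjusted p = 1.29e-05), Nsdhl, a late enzyme of cholesterol synthesis, by 0.98 ± 0.14, Lss by 0.92 ± 0.16 and Insig1 by 0.77 ± 0.15 (adjusted p = 0.000328). Abcg1 was at -0.01 ± 0.13 (adjusted p = 0.974) and Abca1 at -0.16 ± 0.21 (adjusted p = 0.619). The SREBP2 list was lower at 15 of 24 (18 adjusted over the list alone; median -0.63, adjusted p = 1.4e-07, adjusted p = 0.54 with an estimated correlation). Interferon-stimulated genes were lower at 29 of 34 (30 adjusted over the list alone; median -1.18, adjusted p = 2.6e-15, adjusted p = 0.5 with an estimated correlation), including Oas2 (-1.22 ± 0.17), Zbp1 (-1.58 ± 0.23) and Irgm1 (-0.94 ± 0.15). Golgi genes were higher at 14 of 20 (15 adjusted over the list alone; median 0.45, adjusted p = 1.8e-10, adjusted p = 0.29 with an estimated correlation). Kdelr2 rose by 1.05 ± 0.08 (adjusted p = 1.32e-09) and Sec24d by 0.97 ± 0.09.

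Lysosomal genes were lower with itraconazole at 15 and higher at 1 of 26 (17 and 1 adjusted over the list alone; median -0.35, adjusted p = 9.8e-06, adjusted p = 0.61 with an estimated correlation), such as the hexosaminidase Hexa (-0.66 ± 0.11) and the folliculin gene Flcn (-0.83 ± 0.12). ATF4 targets were higher at 12 and lower at 1 of 23 (13 and 1 adjusted over the list alone; adjusted p = 0.00065, adjusted p = 0.67 with an estimated correlation), with Chac1 at 2.65 ± 0.47 and Mthfd2 at 1.61 ± 0.26. The unfolded protein response list was higher at 11 of 20 (16 adjusted over the list alone; adjusted p = 1.2e-06, adjusted p = 0.61 with an estimated correlation), and Ddit3 did not pass (0.34 ± 0.25). Cx3cr1, the fractalkine receptor, rose by 4.17 ± 0.51 (161 ± 24.4 against 8.97 ± 1.75 CPM), Olfml3 by 5.05 ± 0.54, Gpr84 by 3.93 ± 0.46, the stress kinase Plk3 by 3.23 ± 0.25 and Jag1 by 3.04 ± 0.22. Vcam1 fell by 2.76 ± 0.29, the endothelin receptor Ednrb by 2.92 ± 0.34 and the circadian factor Dbp by 2.71 ± 0.35. Tnf rose by 2.18 ± 0.45 (adjusted p = 0.000775) and Il10 fell by 1.22 ± 0.31. The totals were 1900 genes higher and 1633 lower, with 2243 called without untreated mouse 3.

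OSW-1, at the lowest dose, moved the most genes in unstimulated cells, 2643 higher and 2269 lower, and lowered interferon-stimulated genes furthest. Ifit3, an antiviral RNA-binding protein, fell by 3.85 ± 0.35 (6.99 ± 1.04 against 101 ± 23.5 CPM, adjusted p = 6.62e-09), Ifit2 by 3.70 ± 0.44, Iigp1 by 4.59 ± 0.49, Gbp7 by 3.74 ± 0.29, Oas2 by 2.38 ± 0.18 (adjusted p = 3.25e-10) and Zbp1 by 2.77 ± 0.25. The list was lower at 31 of 34 members (33 adjusted over the list alone; median -2.32, adjusted p = 1.4e-25, adjusted p = 0.34 with an estimated correlation). All 24 SREBP2 targets were lower (24 adjusted over the list alone; median -1.74, adjusted p = 4.4e-22, adjusted p = 0.18 with an estimated correlation), with Hmgcs1 at -1.96 ± 0.14, Cyp51 at -2.37 ± 0.18 and Insig1 at -1.80 ± 0.15. Abcg1 rose by 0.89 ± 0.13 and Abca1 by 0.79 ± 0.21.

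Golgi genes were higher with OSW-1 at 17 of 20 (18 adjusted over the list alone; median 0.70, adjusted p = 6.8e-14, adjusted p = 0.18 with an estimated correlation), with Kdelr2 at 1.24 ± 0.08, Sec24d at 1.32 ± 0.09 and the golgin Golga5 at 0.86 ± 0.07. ATF4 targets were higher at 19 and lower at 1 of 23 (median 1.26, adjusted p = 1.4e-08, adjusted p = 0.5 with an estimated correlation). Chac1 rose by 4.44 ± 0.48 (23.3 ± 8.09 against 1.05 ± 0.503 CPM), Nupr1 by 2.23 ± 0.24, Atf4 by 1.71 ± 0.18, Ddit3 by 1.57 ± 0.26 and Atf3 by 0.98 ± 0.28. The unfolded protein response list was higher at 17 of 20 (19 adjusted over the list alone; adjusted p = 1.1e-08, adjusted p = 0.5 with an estimated correlation), with the chaperone Dnajb9 at 1.09 ± 0.10. Immediate early genes were higher at 8 of 15 (9 adjusted over the list alone; median 0.77, adjusted p = 0.00015, adjusted p = 0.34 with an estimated correlation), among them Fos (2.22 ± 0.27) and the phosphatase Dusp1 (2.37 ± 0.19). Inflammatory genes were higher at 9 and lower at 1 of 24 (median 1.65, or 1.38 with members without reads at their bounds; adjusted p = 0.0064, adjusted p = 0.73 with an estimated correlation). Cxcl2 rose by 4.23 ± 0.47 (47.7 ± 15.7 against 2.56 ± 0.663 CPM), Tnf by 2.41 ± 0.45 and Il1b by 1.39 ± 0.39 (adjusted p = 0.00706). Il10 fell by 2.65 ± 0.34. Lysosomal genes were lower at 16 and higher at 3 of 26 (adjusted p = 0.72 with an estimated correlation), with Lamp1 at -0.67 ± 0.10. Olfml3 rose by 5.80 ± 0.54, Cx3cr1 by 4.40 ± 0.51 and the adhesion protein Flrt3 by 4.78 ± 0.44. The lipid carrier Fabp5 fell by 2.21 ± 0.21.

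**Figure D2:**
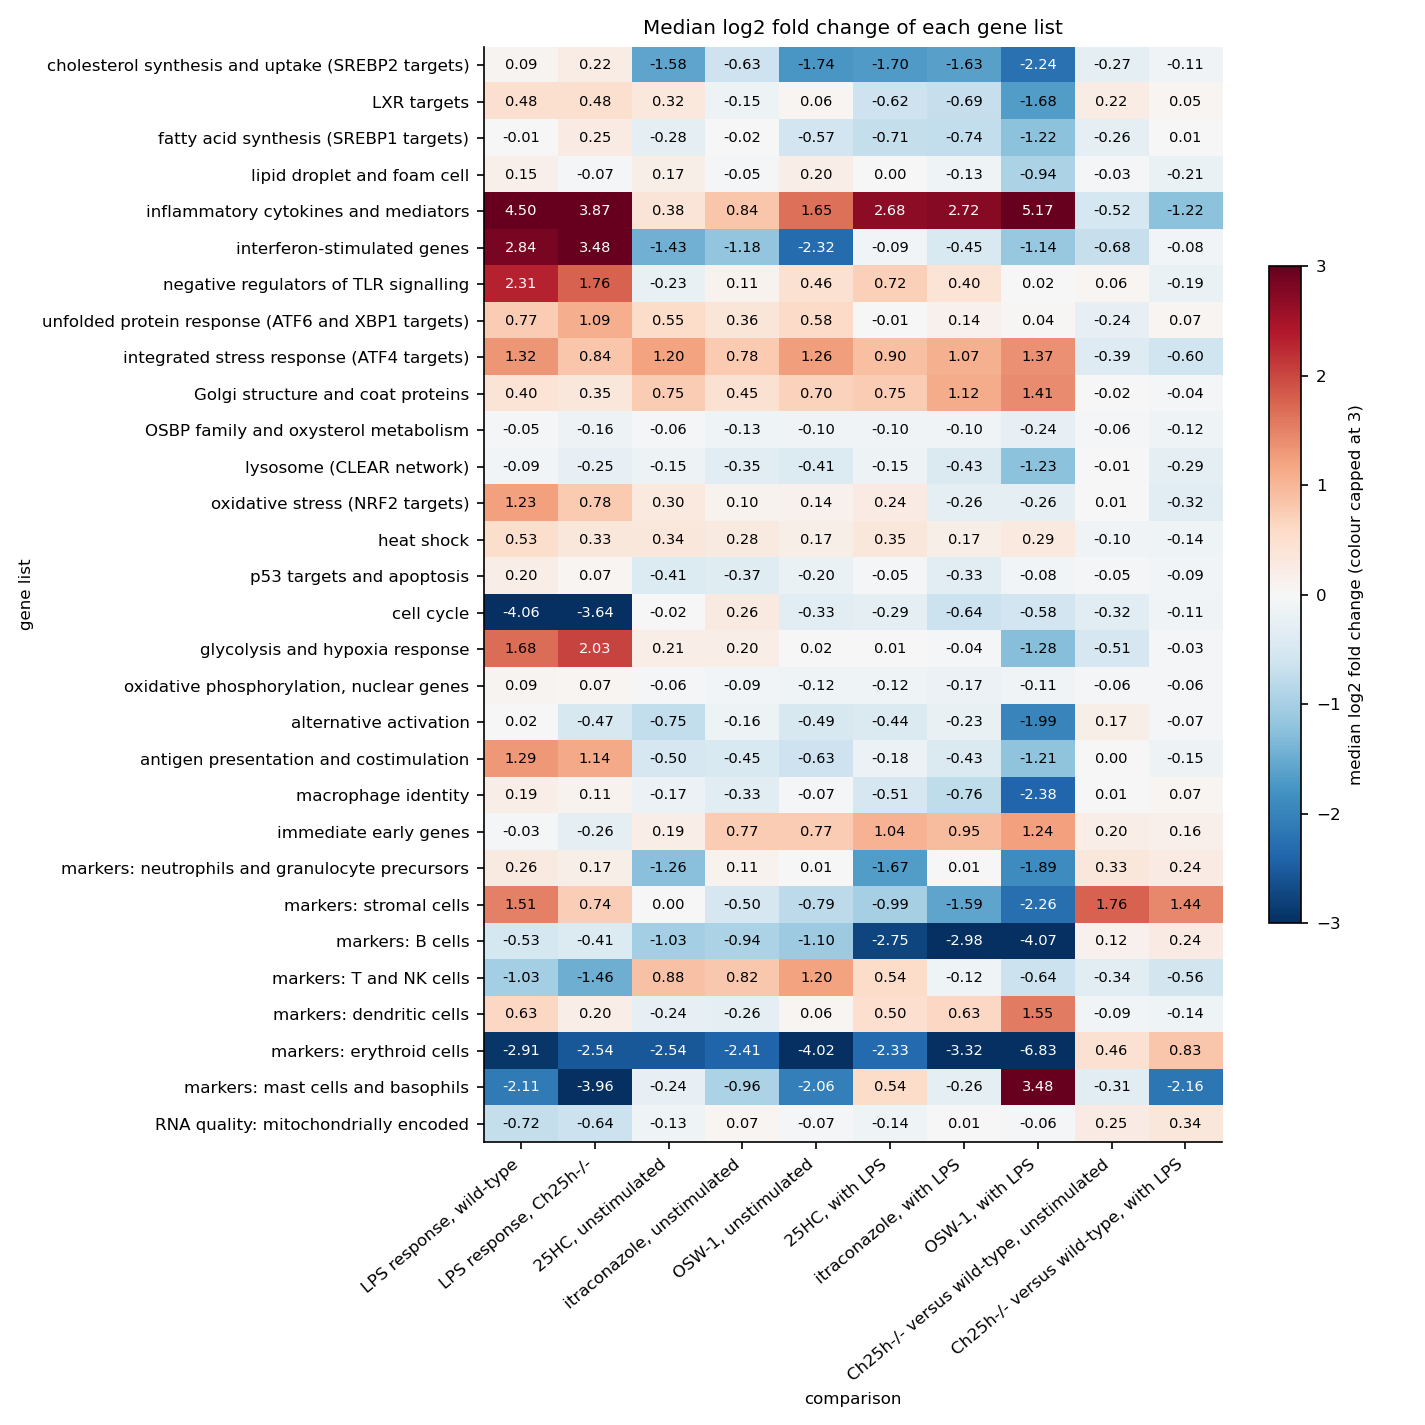
Median log2 fold change of each gene list in each comparison. Colour runs from lower to higher medians.

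The 3 compounds' changes in unstimulated cells overlapped widely. Genes higher with both compounds numbered 1524 for 25HC and itraconazole, 1713 for 25HC and OSW-1 and 1530 for itraconazole and OSW-1, where independent lists would share 303, 421 and 381. Genes lower with both numbered 1233, 1328 and 1271 (independent lists 209, 290 and 281). These comparisons share the untreated libraries. Simulated unchanged groups set against shared simulated controls had 0 genes in common in each of 20 runs. No gene was moved in these runs, so that count was largely fixed in advance and does not bound the effect of shared controls. Fold changes of the simulated groups had covariances of 0.0446, 0.0437 and 0.0445 against the observed 0.371, 0.443 and 0.448. With the other compound of each pair set against Ch25h-/- cells in place of the shared controls, covariances were 0.359 to 0.442. Genes moved the same way by all 3 compounds numbered 1349 higher and 1067 lower, among them Kdelr2 and Olfml3 (higher) and Oas2, Zbp1 and Hmgcs1 (lower).

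**Figure D3:**
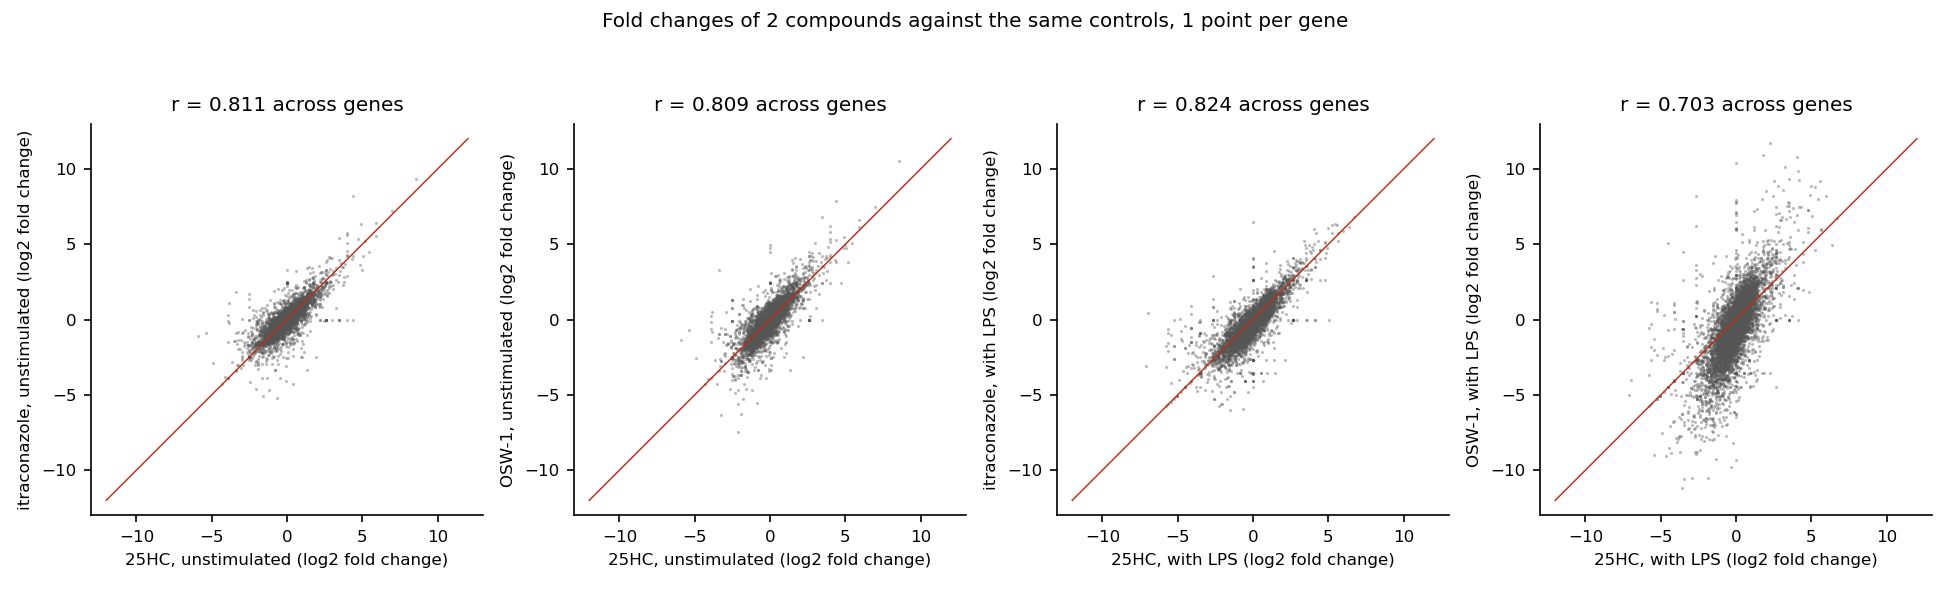
Log2 fold changes of pairs of compounds against shared untreated controls. Unstimulated and LPS-treated cells are drawn apart.

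Direct tests between compounds set itraconazole apart from the other compounds by its cholesterol genes. Each compound was used at a single dose, so compound and dose go together in these tests. 25HC against itraconazole called 31 genes in unstimulated cells, 11 higher and 20 lower. Cyp51 was lower with 25HC by -1.65 ± 0.18 (17.6 ± 1.63 against 55.3 ± 5.16 CPM, adjusted p = 5.41e-06) and Srebf2 by -1.04 ± 0.09. Abcg1 was higher by 1.14 ± 0.13 (adjusted p = 2.83e-05) and Abca1 by 1.09 ± 0.21. The SREBP2 list was lower at 15 of 24 members (23 adjusted over the list alone; median -0.95, adjusted p = 2.8e-61), and it passed with the other setting too (adjusted p = 0.02 with an estimated correlation). Golgi genes were higher with 25HC at 3 of 20 (12 adjusted over the list alone; median 0.28, adjusted p = 0.11 with an estimated correlation). OSW-1 against itraconazole gave 472 genes higher and 362 lower, with Cyp51 at -1.63 ± 0.18, Ifit3 at -2.11 ± 0.33, Chac1 at 1.80 ± 0.40 and Ddit3 at 1.23 ± 0.25. SREBP2 targets were lower at 23 of 24 (median -1.03, adjusted p = 1e-34, adjusted p = 0.1 with an estimated correlation) and interferon-stimulated genes at 24 of 34 (31 adjusted over the list alone; median -1.20, adjusted p = 0.32 with an estimated correlation).

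Between 25HC and OSW-1 interferon-stimulated genes and some inflammatory genes differed. 25HC left Ifit3 1.70 ± 0.33, Ifit1 1.73 ± 0.35, Oas2 0.90 ± 0.17 and Rsad2, an antiviral enzyme, 1.99 ± 0.49 above OSW-1, and Il1b at -3.20 ± 0.48, Cxcl1 at -2.53 ± 0.58 and Olfml3 at -1.84 ± 0.42. Interferon-stimulated genes were higher with 25HC at 17 of 34 (29 adjusted over the list alone; median 0.89, adjusted p = 1e-24, adjusted p = 0.34 with an estimated correlation). Inflammatory genes were lower with 25HC at 4 of 24 (2 higher and 6 lower adjusted over the list alone; median -0.44, adjusted p = 0.0038, adjusted p = 0.72 with an estimated correlation). No SREBP2 target was called (median 0.13; Hmgcs1 0.09 ± 0.13, adjusted p = 0.782, adjusted p = 0.93 with an estimated correlation). The counts between compounds depended on single mice. 25HC against OSW-1 called 177 genes higher and 196 lower, and 86 or 139 without mouse 1 or 2 of the 25HC group and 95 or 124 without mouse 1 or 2 of the OSW-1 group. OSW-1 against itraconazole called 176 or 489 without mouse 1 or 2 of the OSW-1 group and 383 or 295 without mouse 1 or 2 of the itraconazole group. 25HC against itraconazole called 20 without mouse 2 of the 25HC group, and 19 or 20 without mouse 2 or 3 of the itraconazole group.

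Pretreatment with 25HC raised many inflammatory genes above LPS alone and lowered SREBP2 targets. Il6 rose by 5.57 ± 0.48 (185 ± 75.2 against 3.9 ± 2.56 CPM, adjusted p = 5.52e-09), Cxcl1 by 4.99 ± 0.33 (44.3 ± 16.5 against 1.4 ± 0.534 CPM), Cxcl3 by 5.42 ± 0.46, Cxcl2 by 4.07 ± 0.44 and Il1a by 4.46 ± 0.52. Il1b, lower with 25HC before LPS, was higher with LPS by 2.59 ± 0.33 (9450 ± 2190 against 1570 ± 467 CPM, adjusted p = 1.52e-06). Tnf rose by 2.55 ± 0.44, Il12b by 3.31 ± 0.70, the prostaglandin synthase Ptgs2 by 3.81 ± 0.54 and the activin subunit Inhba by 4.75 ± 0.39. Ifnb1 fell by 2.15 ± 0.73 (adjusted p = 0.0271), Il10 by 1.29 ± 0.32 and Cxcl9 by 1.65 ± 0.32. The inflammatory list was higher at 18 and lower at 1 of 24 (20 and 1 adjusted over the list alone; median 2.68, adjusted p = 3.9e-08, adjusted p = 0.5 with an estimated correlation). Interferon-stimulated genes stayed near the level of LPS alone, 1 higher and 3 lower of 34 (median -0.09, adjusted p = 0.54). All 24 SREBP2 targets were lower (median -1.70, adjusted p = 1e-21, adjusted p = 0.18 with an estimated correlation), with Cyp51 at -2.59 ± 0.18 (12.3 ± 1.08 against 74.4 ± 14.6 CPM). The desaturase Fads2, of the fatty acid synthesis list, was at -3.95 ± 0.41.

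Golgi genes were higher with 25HC and LPS at 19 of 20 members (19 adjusted over the list alone; median 0.75, adjusted p = 3.7e-14, adjusted p = 0.18 with an estimated correlation), with Kdelr2 at 1.02 ± 0.08 and the coatomer subunit Copg1 at 0.85 ± 0.08. ATF4 targets were higher at 15 of 23 (median 0.90, adjusted p = 0.57 with an estimated correlation), with Slc7a11 at 3.49 ± 0.39, and immediate early genes at 12 of 15 (median 1.04, adjusted p = 0.18 with an estimated correlation), with Nr4a1 at 2.96 ± 0.40. Fatty acid synthesis genes were lower at 8 of 14 (9 adjusted over the list alone; median -0.71, adjusted p = 0.00032, adjusted p = 0.5 with an estimated correlation). Macrophage identity genes were lower at 11 and higher at 2 of 20 (median -0.51, adjusted p = 0.026, adjusted p = 0.69 with an estimated correlation). The phagocytic receptor Mertk fell by 1.25 ± 0.21, while the LPS co-receptor Cd14 rose by 2.22 ± 0.16. Mrc1 (-2.45 ± 0.27) and Cbr2 (-4.02 ± 0.28) were lower. The totals were 2746 genes higher and 2766 lower.

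Itraconazole acted on LPS-treated cells in the same directions. Il6 rose by 6.25 ± 0.49 (297 ± 132 CPM, adjusted p = 3.98e-10), Cxcl1 by 6.04 ± 0.33 (92.4 ± 23.4 CPM), Cxcl3 by 6.37 ± 0.48, Cxcl2 by 5.01 ± 0.46, Il1b by 2.82 ± 0.33, Tnf by 2.62 ± 0.44 and the protease inhibitor Serpinb2 by 4.58 ± 0.47. Nos2 was at 0.58 ± 0.45 (adjusted p = 0.288). The inflammatory list was higher at 18 and lower at 1 of 24 (18 and 1 adjusted over the list alone; median 2.72, adjusted p = 3.1e-06, adjusted p = 0.55 with an estimated correlation). Interferon-stimulated genes were lower at 15 of 34 (15 adjusted over the list alone; median -0.45, adjusted p = 0.015, adjusted p = 0.87 with an estimated correlation), with Cxcl9 at -2.16 ± 0.33, Iigp1 at -1.75 ± 0.33 and the RNA sensor Ifih1 at -0.57 ± 0.14. All 24 SREBP2 targets were lower, more of them than in unstimulated cells (median -1.63, adjusted p = 3.3e-14, adjusted p = 0.36 with an estimated correlation). Dhcr7 was at -2.87 ± 0.19 and Msmo1 at -2.38 ± 0.17. The desaturase Scd1 fell by 3.76 ± 0.40. All 20 Golgi genes were higher (median 1.12, adjusted p = 5.6e-15, adjusted p = 0.18 with an estimated correlation). Kdelr2 rose by 1.54 ± 0.08 (202 ± 10.8 against 69.6 ± 2.53 CPM, adjusted p = 3.93e-13), Copb2 by 1.17 ± 0.08 and Golga5 by 1.01 ± 0.07. Osbp rose by 0.84 ± 0.09 and Col4a3bp, the ceramide carrier, by 1.44 ± 0.12. Lysosomal genes were lower at 19 and higher at 2 of 26 (median -0.43, adjusted p = 0.72 with an estimated correlation), with Hexa at -1.16 ± 0.12, and macrophage identity genes at 13 of 20 (median -0.76, adjusted p = 0.61 with an estimated correlation), with Mertk at -2.05 ± 0.22 and Cd68 at -0.99 ± 0.13. In total 3488 genes were higher and 3676 lower.

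OSW-1 with LPS shifted most tested genes, 4516 higher and 4887 lower. It raised a broad set of cytokines: Csf2, the granulocyte-macrophage growth factor, by 11.70 ± 0.62 (551 ± 207 against 0.163 ± 0.188 CPM, adjusted p = 1.67e-11), the fractalkine gene Cx3cl1 by 9.22 ± 0.51, Il6 by 9.16 ± 0.55 (2230 ± 659 CPM, adjusted p = 2.52e-13), Cxcl1 by 8.87 ± 0.36 (653 ± 59.4 CPM, adjusted p = 6.01e-16), the chemokine Ccl22 by 7.97 ± 0.49 (1430 ± 551 CPM), Il12b by 6.64 ± 0.80 (645 ± 134 CPM) and Tnf by 3.87 ± 0.47 (816 ± 217 against 56 ± 31.9 CPM). Il1b rose by 2.84 ± 0.33. In the other direction Nos2 fell by 3.50 ± 0.50 (37.5 ± 9.38 against 425 ± 258 CPM, adjusted p = 1.25e-06), Ptges by 1.18 ± 0.25 (0.11 against Ch25h-/- cells with LPS, not passing) and Cxcl9 by 5.74 ± 0.42. Ifnb1 had 0 counts and was at least 26.7-fold lower. The inflammatory list was higher at 18 and lower at 2 of 24 (18 and 2 adjusted over the list alone; median 5.17, adjusted p = 2.2e-05, adjusted p = 0.61 with an estimated correlation). Interferon-stimulated genes were lower at 23 and higher at 1 of 34 (23 and 1 adjusted over the list alone; median -1.14, adjusted p = 0.00046, adjusted p = 0.78 with an estimated correlation).

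Macrophage and lysosomal genes dropped steeply with OSW-1 and LPS. Macrophage identity genes were lower at 17 and higher at 2 of 20 (17 and 2 adjusted over the list alone; median -2.38, adjusted p = 4.3e-05, adjusted p = 0.48 with an estimated correlation). Cd68, a lysosomal glycoprotein, fell by 3.46 ± 0.15 (125 ± 10.6 against 1380 ± 323 CPM) and Mertk by 5.62 ± 0.28, and Cd14 rose by 2.43 ± 0.16. The extracellular matrix gene Tgfbi fell by 8.19 ± 0.55 (5.63 ± 6.47 against 1670 ± 224 CPM), Mrc1 by -6.05 ± 0.34 and Ly6a by -8.65 ± 0.56. Lysosomal genes were lower at 20 and higher at 2 of 26 (median -1.23, adjusted p = 4.9e-06, adjusted p = 0.61 with an estimated correlation), the cathepsin Ctsb by -3.16 ± 0.13 (2040 ± 40.6 against 18200 ± 3720 CPM). The sterol carrier Npc2, of the OSBP family and oxysterol list, was at -2.50 ± 0.15. Glycolysis genes were lower at 18 and higher at 1 of 22 (median -1.28, adjusted p = 0.72 with an estimated correlation), with Pfkfb3 at -3.55 ± 0.17. Antigen presentation went both ways, 14 lower and 2 higher of 19 (median -1.21, adjusted p = 0.67 with an estimated correlation). H2-DMb1, which loads class II peptides, fell by 4.83 ± 0.29, and the costimulatory Cd80 and Cd40 rose by 3.01 ± 0.21 and 3.05 ± 0.28.

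SREBP2 targets were lower with OSW-1 and LPS at 23 of 24 (median -2.24, adjusted p = 2.4e-09, adjusted p = 0.5 with an estimated correlation), with Dhcr7 at -4.28 ± 0.22 and the sterol carrier Stard4 at -3.81 ± 0.23. All 20 Golgi genes were higher (median 1.41, adjusted p = 2.7e-10, adjusted p = 0.29 with an estimated correlation), with Kdelr2 at 2.03 ± 0.08 (284 ± 6.19 against 69.6 ± 2.53 CPM, adjusted p = 2.09e-16) and Copb2 at 1.58 ± 0.08. Osbp rose by 1.09 ± 0.09. ATF4 targets were higher at 17 and lower at 1 of 23 (median 1.37, adjusted p = 0.63 with an estimated correlation), with the folate enzyme Aldh1l2 at 5.79 ± 0.37. Mitochondrially encoded genes were lower at 4 of 13 (3 adjusted over the list alone; median -0.06, adjusted p = 0.76), and their share of counts was 1.04% with OSW-1 and LPS against 1.06% with LPS alone.

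Against LPS alone, pairs of compounds again moved many genes together: 2414 higher and 2455 lower for 25HC and itraconazole (independent lists 727 and 772), 2291 and 2454 for 25HC and OSW-1 (941 and 1026), and 3097 and 3315 for itraconazole and OSW-1 (1196 and 1364). Simulated unchanged groups shared 0 genes, a count largely fixed in advance because no gene was moved. Their covariance was 0.0412 to 0.0414 where 0.702, 1.05 and 1.28 were observed. Against Ch25h-/- cells with LPS for the other compound of each pair, covariances were 0.682 to 1.29. Genes common to all 3 compounds numbered 2162 higher and 2301 lower, with Il6, Cxcl1 and Kdelr2 among the higher and Mertk and Hmgcs1 among the lower. Opposite calls numbered 152 for 25HC and OSW-1 and 100 for itraconazole and OSW-1.

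With LPS, the OSW-1 libraries held odd and even counts and those of 25HC and itraconazole even counts only. Doses differed too, so compound, dose and kind of counts go together in tests of OSW-1 against the others. Direct tests with LPS placed OSW-1 apart. Against 25HC it had more Csf2 (25HC minus OSW-1 -9.45 ± 0.53), Ccl22 (-6.28 ± 0.45), Il6 (-3.59 ± 0.42, adjusted p = 7.06e-08) and Il12b (-3.34 ± 0.67), and less Nos2 (4.68 ± 0.52), Cd68 (3.13 ± 0.14) and Mertk (4.37 ± 0.28). Lysosomal genes were higher with 25HC at 22 and lower at 2 of 26 (median 1.07, adjusted p = 0.5 with an estimated correlation), interferon-stimulated genes higher at 31 of 34 (median 1.17, adjusted p = 0.72 with an estimated correlation) and Golgi genes lower at 18 of 20 (median -0.65, adjusted p = 0.39 with an estimated correlation). These comparisons called 4011 genes higher and 3727 lower. OSW-1 against itraconazole gave 3041 higher and 3358 lower, with Il6 at 2.91 ± 0.40, Nos2 at -4.08 ± 0.51, Cd68 at -2.47 ± 0.14 and Ch25h at -2.31 ± 0.61 (adjusted p = 0.0029). 25HC against itraconazole called 369 genes higher and 492 lower, with Serpinb2 at -3.17 ± 0.43, Cxcl1 at -1.06 ± 0.25, Kdelr2 at -0.51 ± 0.07 and Abcg1 at 0.94 ± 0.13. Golgi genes were lower with 25HC at 14 of 20 (16 adjusted over the list alone; median -0.33, adjusted p = 0.18 with an estimated correlation). The count of genes called for 25HC against itraconazole was 99 without mouse 1 of the 25HC group, and 457, 284 or 1312 without mouse 1, 2 or 3 of the itraconazole group. With the compared groups alone edgeR called no gene in this comparison, while 2974 had an unadjusted p under 0.05 in the full fit.

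**Figure D4:**
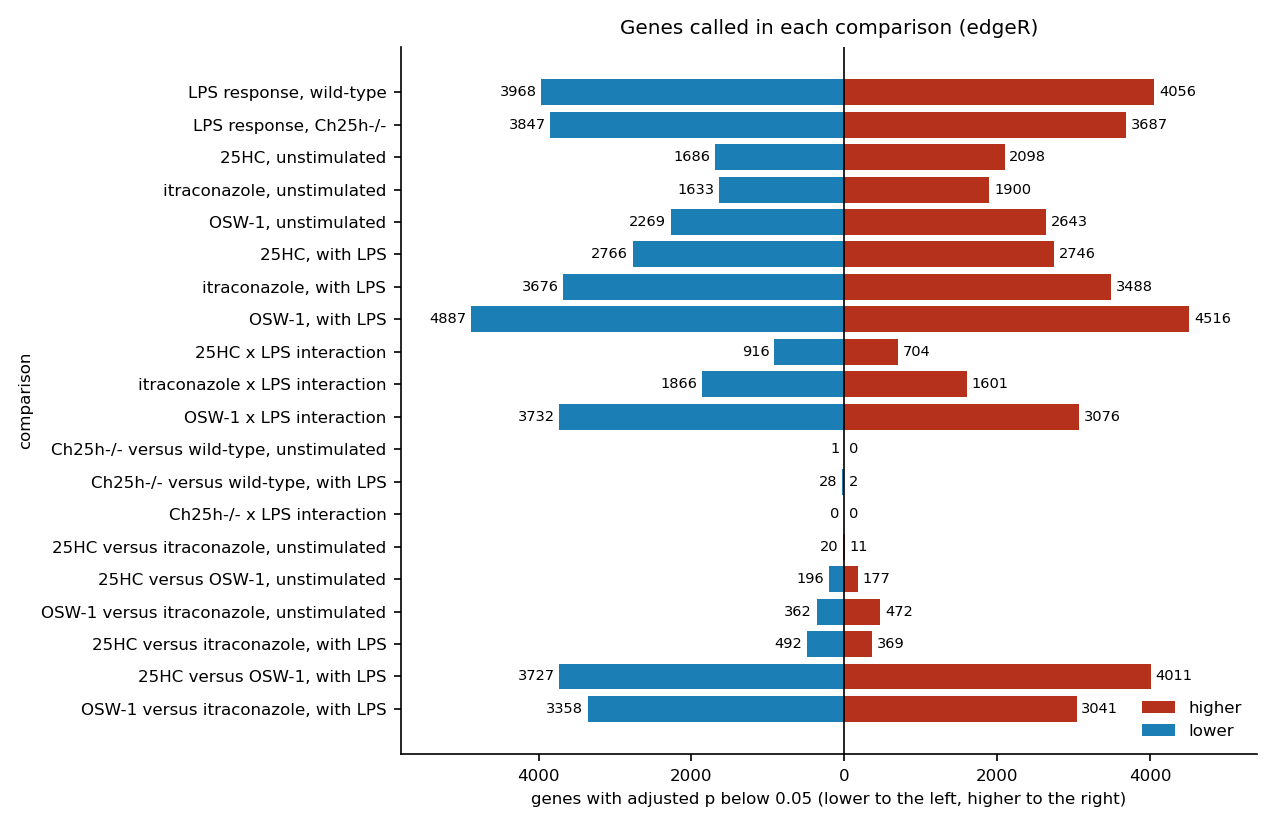
Genes called higher and lower in each of the 20 comparisons.

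The difference between LPS-treated and unstimulated cells was itself changed by each compound. Unstimulated cells were collected at time 0, so a compound effect that changes over 18 more hours of culture is part of these values. Higher and lower here give the sign of that change, and for a gene that LPS lowers a lower value is a deeper fall. For 25HC, 704 genes had a higher LPS fold change than in untreated cells and 916 a lower one: Il1b by 4.39 ± 0.61 (adjusted p = 6.73e-05), Cxcl1 by 4.61 ± 1.11, the matrix protein Thbs1 by 4.15 ± 0.60 and the stress gene Ddit4 by 2.54 ± 0.23 (adjusted p = 9.25e-07), and Olfml3 by -5.52 ± 0.77. The LPS fold change of interferon-stimulated genes was higher at 21 of 34 (30 adjusted over the list alone, median 1.24, adjusted p = 2.8e-14, adjusted p = 0.5 with an estimated correlation), with Gbp3 at 2.27 ± 0.43, Zbp1 at 1.66 ± 0.32 and Oas2 at 1.18 ± 0.24. These genes started lower with 25HC before LPS, and with LPS most stayed near the level of LPS alone. The LPS fold change of the unfolded protein response list was lower at 11 of 20 (16 adjusted over the list alone, median -0.54, adjusted p = 0.5 with an estimated correlation), led by Calr (-1.18 ± 0.19). The count of 1620 was 1014 without unstimulated untreated mouse 3, 1037 or 1030 without unstimulated 25HC mouse 1 or 2, and 1062 or 889 without LPS-treated 25HC mouse 1 or 2.

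With itraconazole, 1601 genes had a higher LPS fold change than in untreated cells and 1866 a lower one. SREBP2 targets were lower in it at 20 of 24 (median -1.12, adjusted p = 7.6e-11, adjusted p = 0.5 with an estimated correlation), with Msmo1 at -1.92 ± 0.23, Dhcr7 at -2.03 ± 0.26, Cyp51 at -1.59 ± 0.24 and Srebf2 at -0.87 ± 0.13. Srebf1, of the LXR list, was at -0.82 ± 0.14. The Golgi list was higher in it at 16 of 20 (17 adjusted over the list alone; median 0.54, adjusted p = 7.5e-11, adjusted p = 0.29 with an estimated correlation), with the SNARE protein Stx5a at 1.14 ± 0.13 and Arf4 at 0.89 ± 0.13. With OSW-1, 3076 genes had a higher LPS fold change and 3732 a lower one: Cx3cl1 by 9.62 ± 0.63, Ccl22 by 6.51 ± 1.37 and Il10 by 2.64 ± 0.46, against Tgfbi by -8.88 ± 0.66, Cx3cr1 by -8.43 ± 1.01, Trem2 by -4.08 ± 0.31, Cd68 by -2.91 ± 0.19 and Ch25h by -3.93 ± 0.85. All 22 glycolysis genes had a lower LPS fold change with OSW-1 (median -1.47, adjusted p = 3.4e-07, adjusted p = 0.61 with an estimated correlation), including Pfkfb3 (-3.54 ± 0.23). So did 20 of 26 lysosomal genes (median -1.02, adjusted p = 0.61 with an estimated correlation) and 16 of 20 macrophage identity genes (median -2.41, adjusted p = 0.34 with an estimated correlation).

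Few single genes were called between Ch25h-/- and wild-type cells. The deleted gene Ch25h was not among them, so few calls do not mean few changes. In LPS-treated cells 2 genes were higher than in wild-type, Trpv4 (0.93 ± 0.18) and Rnls (1.02 ± 0.20), both named after their values were seen. Lower were 28: Ap1s3, an adaptor for vesicle sorting, by -1.72 ± 0.26 (adjusted p = 0.00332), Rcl1 by -1.45 ± 0.21 (adjusted p = 0.00332), the integrin Itgb8 by -1.72 ± 0.36, the adenosine receptor Adora2a by -1.57 ± 0.33, Ptges by -1.29 ± 0.25 (344 ± 94.4 against 841 ± 384 CPM, adjusted p = 0.0293), the mitotic kinesin Kif20a by -1.27 ± 0.22 and the NF-kB inhibitor Nfkbia by -0.84 ± 0.17 (adjusted p = 0.0362). Ptgs2 (-2.38 ± 0.52, adjusted p = 0.0517), Il6 (-2.60 ± 0.64, adjusted p = 0.0711), Tnf (-1.63 ± 0.44, adjusted p = 0.0949) and Il1b (0.06 ± 0.31, adjusted p = 0.946) did not pass, nor did Ch25h itself (-3.66 ± 1.02, adjusted p = 0.107). The inflammatory list was lower at 1 of 24 (10 adjusted over the list alone; median -1.22, or -1.03 with members without reads at their bounds; adjusted p = 4.2e-06, adjusted p = 0.55 with an estimated correlation). Lysosomal genes were lower at 0 of 26 (10 adjusted over the list alone; median -0.29, adjusted p = 1.6e-07, adjusted p = 0.54 with an estimated correlation), a count that was 0 with edgeR while 2257 genes of all tested had an unadjusted p under 0.05. DESeq2 called 230 genes and limma-voom 1 in this comparison. Mitochondrially encoded RNA was 1.313% of counts (1.262 to 1.398%) without Ch25h against 1.059% (0.9605 to 1.225%) in wild-type, so its share differs along with these lists. The count was 3, 4 or 2396 without LPS-treated wild-type mouse 1, 2 or 3, and 0, 9 or 6 without Ch25h-/- mouse 1, 2 or 3.

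In unstimulated cells edgeR called 1 gene, Asah2, a ceramidase (-0.81 ± 0.10, named after its value was seen), while 1717 had an unadjusted p under 0.05, DESeq2 called 129 and limma-voom 15. Ch25h was at -4.11 ± 0.95 (0.118 ± 0.143 against 1.96 ± 0.466 CPM, adjusted p = 0.0941). Some lists leaned at the preset correlation, but those given here did not pass with an estimated one. Interferon-stimulated genes had a median of -0.68 (0 of 34 called, 21 lower adjusted over the list alone, adjusted p = 3.8e-14, adjusted p = 0.5 with an estimated correlation), with Usp18 at -1.07 ± 0.29 (adjusted p = 0.141). Glycolysis genes had a median of -0.51 (16 lower adjusted over the list alone; adjusted p = 3.3e-12, adjusted p = 0.48 with an estimated correlation), with Eno1 at -0.63 ± 0.15 (adjusted p = 0.0999). Stromal markers leaned higher (median 1.76, 8 of 10 adjusted over the list alone; adjusted p = 2.6e-07, adjusted p = 0.18 with an estimated correlation), with the collagen Col1a2 at 1.74 ± 0.43 (adjusted p = 0.113) and Sparc at 1.58 ± 0.46. Mitochondrially encoded genes had a median of 0.25 (adjusted p = 0.0014, adjusted p = 0.66 with an estimated correlation). Their share was 1.92 ± 0.0724% without Ch25h against 1.63 ± 0.0662% in wild-type. The count was 361 without wild-type mouse 3 and 58 without Ch25h-/- mouse 2. For the difference between the genotypes' LPS responses edgeR called 0 genes, with 1476 at an unadjusted p under 0.05, 8 called by DESeq2 and 1 by limma-voom. That count was 716 without LPS-treated wild-type mouse 3, 2 without unstimulated wild-type mouse 3, and 1 without unstimulated Ch25h-/- mouse 2 or LPS-treated Ch25h-/- mouse 3. The genotypes come from different animals. Their libraries also differ in kind of counts, even only in untreated wild-type and odd and even in Ch25h-/-. Animal, kind of counts and genotype therefore go together in all comparisons of genotypes, with LPS too.

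**Figure D5:**
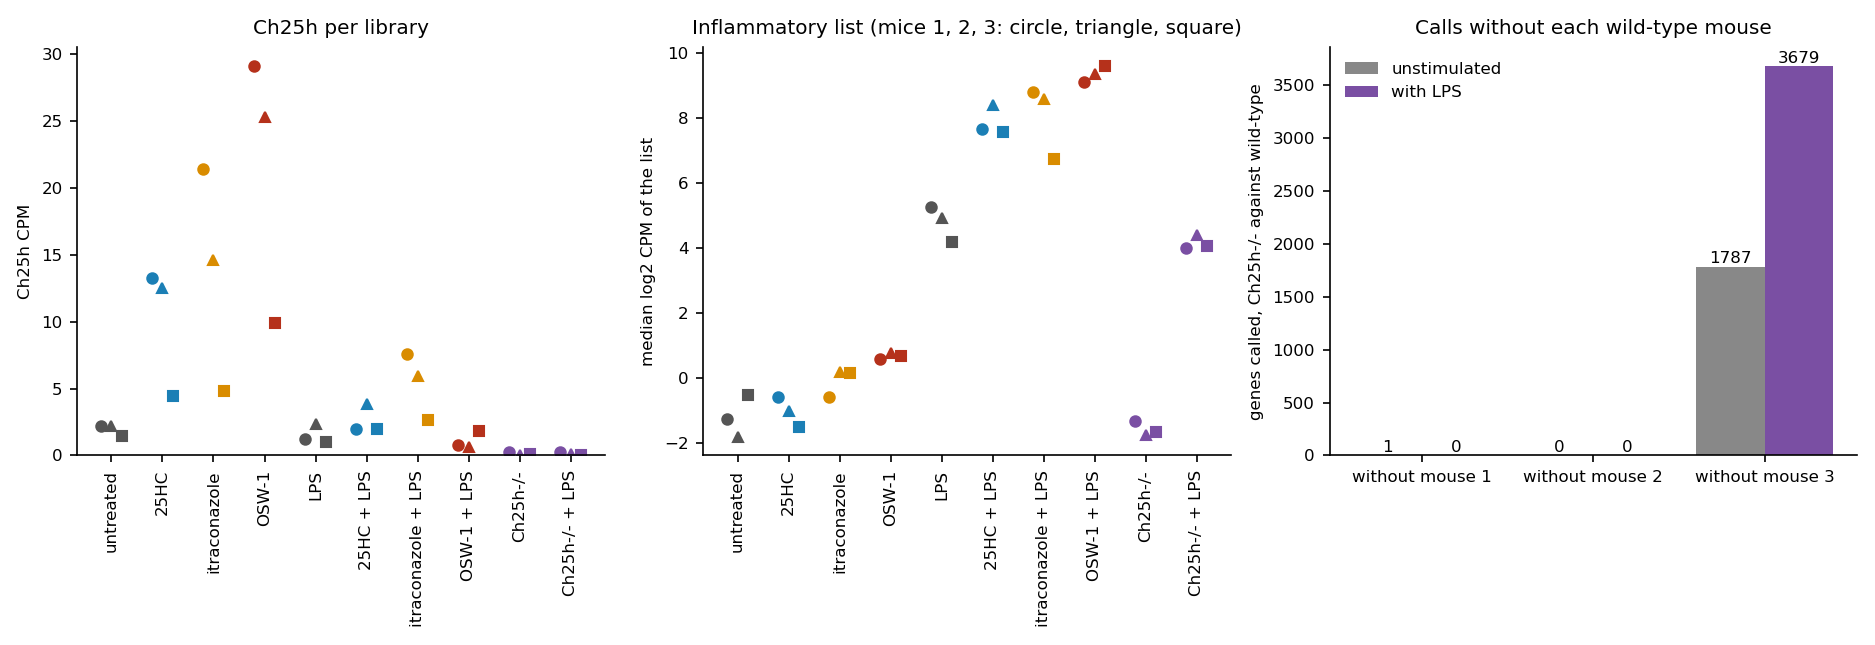
Ch25h levels and inflammatory list medians in each library, and genes called between genotypes without each wild-type mouse.

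The remaining gene lists are given here for some of the comparisons. LXR targets with LPS alone were 7 higher and 1 lower of 14 (median 0.48, adjusted p = 0.31), with the receptor gene Nr1h3 at 2.50 ± 0.20 and Arl4c at -1.37 ± 0.11. With OSW-1 and LPS they were 3 higher and 9 lower (median -1.68, adjusted p = 0.067). Fatty acid synthesis genes were 0 higher and 8 lower of 14 with OSW-1 before LPS (median -0.57, adjusted p = 0.0078, adjusted p = 0.61 with an estimated correlation). Lipid droplet genes split, 5 higher and 1 lower of 14 with 25HC before LPS (median 0.17, adjusted p = 0.5), with the lipase Lpl at 0.78 ± 0.16 and Fabp5 at -1.31 ± 0.21. OSBP family and oxysterol genes split as well, 4 higher and 3 lower of 21 with 25HC before LPS (median -0.06, adjusted p = 0.73) and 4 higher and 11 lower with OSW-1 and LPS (median -0.24, adjusted p = 0.27). Osbpl11 fell by 0.80 ± 0.10 with 25HC, and LPS alone raised Osbpl3 by 2.39 ± 0.21 and the sterol hydroxylase Cyp27a1 was lower at -2.60 ± 0.39. Heat shock genes were higher with 25HC before LPS at 8 of 15 (median 0.34, adjusted p = 0.0018, adjusted p = 0.66 with an estimated correlation), led by Hsph1 (1.07 ± 0.13).

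p53 targets were 1 higher and 7 lower of 18 with 25HC before LPS (median -0.41, adjusted p = 0.028, adjusted p = 0.76 with an estimated correlation), with the sestrin Sesn1 at -1.75 ± 0.28. Nuclear genes of oxidative phosphorylation were 0 higher and 6 lower of 20 with OSW-1 before LPS (median -0.12, adjusted p = 0.027, adjusted p = 0.76 with an estimated correlation), the cytochrome oxidase subunit Cox5a by -0.38 ± 0.08. Alternative activation genes split 6 and 6 of 13 with LPS alone (median 0.02). The interleukin-4 receptor Il4ra rose by 2.97 ± 0.22 and the lectin Clec10a fell by 3.66 ± 0.33. The transcription factor Klf4 of this list rose with 25HC (1.32 ± 0.17) and with OSW-1 (2.33 ± 0.18) before LPS. Macrophage identity genes were 8 higher and 5 lower of 20 with LPS alone (median 0.19), with Emr1 (F4/80) at 1.66 ± 0.13 and the lipid receptor Trem2 at -2.18 ± 0.22, and immediate early genes split 5 and 5 of 15 (median -0.03).

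Markers of other cells were tested as lists too. With LPS alone neutrophil markers were 2 higher and 2 lower of 7 (median 0.26), stromal markers 4 higher and 1 lower of 10 (median 1.51; the proteoglycan Dcn rose by 4.97 ± 0.56), dendritic cell markers 1 higher and 1 lower of 4, and T and NK cell markers 1 higher of 3. The B cell list held 1 tested gene, Cd79b (-0.53 ± 0.36, adjusted p = 0.203), the erythroid list Epor (-2.91 ± 0.57) and the mast cell list Kit (-2.11 ± 0.62). With OSW-1 and LPS stromal markers were 2 higher and 7 lower (median -2.26, adjusted p = 0.45), neutrophil markers 1 higher and 5 lower (median -1.89, adjusted p = 0.72), and Kit rose by 3.48 ± 0.62.

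Genes that LPS moved in Ch25h-/- cells by a log2 fold change of 2 or more, a choice of genes that uses no wild-type library, were then followed in wild-type cells. Of the 534 induced genes, 102 were higher and 310 lower with OSW-1 and LPS than with LPS alone (median -1.13, adjusted p = 0.000105, adjusted p = 0.249 with an estimated correlation), Nos2 and Cxcl9 among the lower. The induced set split with 25HC, 111 higher and 127 lower (median -0.09, adjusted p = 0.626), and with itraconazole, 110 higher and 170 lower (median -0.30, adjusted p = 0.219). Of the 693 repressed genes, 259 were lower and 87 higher with itraconazole and LPS (median -0.58, adjusted p = 0.00199, adjusted p = 0.0129 with an estimated correlation), and 201 lower and 86 higher with 25HC and LPS (median -0.40, adjusted p = 0.0151, adjusted p = 0.0436 with an estimated correlation). With OSW-1 and LPS 286 were lower and 144 higher (median -0.64, adjusted p = 0.0768). Before LPS 148 were lower and 36 higher with 25HC (median -0.23, adjusted p = 0.00305 with an estimated correlation), and 196 lower and 55 higher with OSW-1 (median -0.34, adjusted p = 0.00305 with an estimated correlation). With itraconazole 135 were lower and 54 higher (median -0.08, adjusted p = 0.0542 with an estimated correlation).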

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

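The searches for genes moved in opposite directions and the comparison with Ch25h-/- controls were chosen only after the results were seen, while the tests of LPS response differences were planned.

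Each compound's effect differed between unstimulated and LPS-treated cells at many genes: 1620 for 25HC, 3467 for itraconazole and 6808 for OSW-1, by edgeR with 3 mice per group. Genes called in opposite directions before and with LPS, and in the difference, numbered 132 for 25HC (69 lower then higher, 63 higher then lower), 194 for itraconazole (78 and 116) and 423 for OSW-1 (129 and 294). Leaving out single libraries gave 889 to 2076 for 25HC, with 1014 without unstimulated untreated mouse 3, 1037 or 1030 without unstimulated 25HC mouse 1 or 2, and 1062 or 889 without LPS-treated 25HC mouse 1 or 2. The ranges were 2503 to 4378 for itraconazole and 6264 to 6930 for OSW-1.

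Il1b changed direction with 25HC. It was lower with 25HC before LPS (-1.80 ± 0.53) and higher with LPS (2.59 ± 0.33), a difference of 4.39 ± 0.61 (adjusted p = 6.73e-05). The unstimulated level was low, 0.415 ± 0.209 against 1.49 ± 1.02 CPM, and the libraries of the groups overlapped there. Over the tools and normalizations tried, the Il1b difference was 4.09 to 4.44.

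Srebf1, which drives fatty acid synthesis, was 0.31 ± 0.10 higher with itraconazole before LPS and -0.51 ± 0.10 lower with LPS, a difference of -0.82 ± 0.14 (adjusted p = 0.000125). The Srebf1 difference was -0.69 without wild-type mouse 3.

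Counts are all even in 20 libraries and odd and even in 9, OSW-1 with LPS and the Ch25h-/- cells, for a reason that was not tested. Dividing the even counts by 2 changed the Ch25h-/- against wild-type counts, to 6 genes unstimulated and 58 with LPS, and left the other 18 comparisons within 1.5 times their counts.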

How the results depend on the processing

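Halved counts, Ch25h-/- controls and the removal of wild-type mouse 3 were chosen only after the values were seen, and all other settings here were planned.

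The comparisons of genotypes depended on the settings most. Unstimulated Ch25h-/- against wild-type cells called 1 gene as reported, 5 with DESeq2 size factors, 2 without the filter, 139 with the mouse as a replicate block, 30 with the number shared between genotypes, 129 with DESeq2, 0 with the compared groups alone in edgeR (1717 with an unadjusted p under 0.05 in the full fit), 15 with limma-voom, 6 with halved counts and 1787 without wild-type mouse 3. With LPS the 30 genes became 81 without the filter, 203 with the block, 78 with the shared number, 230 with DESeq2, 0 with the compared groups alone, 1 with limma-voom, 58 with halved counts and 3679 without wild-type mouse 3. For the difference of LPS responses, 0 genes by edgeR became 8 with DESeq2, 1 with limma-voom and 2182 without wild-type mouse 3, with 1476 at an unadjusted p under 0.05.

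Direct comparisons of compounds in unstimulated cells came next. 25HC against itraconazole called 31 genes, and 67 with the block, 111 with DESeq2, 83 with the compared groups alone, 102 with limma-voom and 88 without wild-type mouse 3. 25HC against OSW-1 called 373, and 642 with the block, 714 with DESeq2, 808 with limma-voom and 1238 without mouse 3. OSW-1 against itraconazole called 834, and 1313 with DESeq2, 1924 with the compared groups alone, 1637 with limma-voom and 1808 without mouse 3. With LPS, 25HC against itraconazole called 861, 0 with the compared groups alone in edgeR (2974 at an unadjusted p under 0.05 in the full fit) and 2132 without mouse 3.

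The effects of single compounds moved less. With the compared groups alone the counts fell to 3215 for 25HC with LPS, 4571 for itraconazole with LPS, 903 for the 25HC response difference and 2292 for that of itraconazole. The 25HC response difference rose to 2771 without wild-type mouse 3. Against Ch25h-/- controls unstimulated itraconazole called 5335 genes, 3154 of them shared in direction with the 3533 against wild-type controls.

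Leaving out single libraries gave ranges of 7307 to 8154 for the wild-type LPS response, 6871 to 7174 for Ch25h-/-, 2359 to 4032, 2243 to 3209 and 3733 to 4565 for unstimulated 25HC, itraconazole and OSW-1, and 4109 to 5225, 6168 to 7364 and 8927 to 9326 with LPS. The differences of response ranged over 889 to 2076, 2503 to 4378 and 6264 to 6930. Genotype comparisons ranged over 1 to 361, 0 to 2396 and 0 to 716, with the high ends all without wild-type mouse 3. Compounds against each other ranged over 19 to 32, 86 to 334 and 176 to 677 unstimulated and 99 to 1312, 7012 to 7439 and 5437 to 6151 with LPS.

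Single genes reversed sign in 4 cases. With Ch25h-/- controls for OSW-1 with LPS, Ptges was at 0.11, Hspa1a at 0.16 and Ch25h, low in those controls by design, at 3.17. Mmp8 with unstimulated OSW-1 was at -1.1 without wild-type mouse 3. Of the LPS-regulated sets, repressed genes with unstimulated itraconazole (-0.08, adjusted p = 0.0542), induced genes with OSW-1 and LPS (-1.13, adjusted p = 0.249) and induced genes in the OSW-1 response difference (-0.96, adjusted p = 0.249) lost significance with an estimated correlation. With sets at a log2 fold change of 1, repressed genes with OSW-1 and LPS (-0.56, adjusted p = 0.0146) and the induced (-0.25, adjusted p = 0.0132) and repressed (-0.31, adjusted p = 0.0391) genes in the itraconazole response difference gained it, the last 2 not with an estimated correlation (adjusted p = 0.559 and 0.059).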

Other observations

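Tests of the OSW-1 shift, of interferon genes against Ch25h-/- controls and of wild-type mouse 3, and the sorting of splits by LPS libraries, were chosen only after the results were seen, while the regrouping of libraries and the gene lists were planned.

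Before LPS OSW-1 raised the fractalkine receptor Cx3cr1 by 4.40 ± 0.51, as itraconazole did (4.17 ± 0.51). With LPS, OSW-1 raised the ligand Cx3cl1 by 9.22 ± 0.51, and levels with 25HC and LPS were below those with OSW-1 (-6.72 ± 0.41). The LPS response of Cx3cr1 differed by -8.43 ± 1.01 with OSW-1, -3.44 ± 0.77 with 25HC and -2.83 ± 0.72 with itraconazole. OSW-1 with LPS also raised the chemokine Ccl17 by 5.21 ± 0.72, the nuclear receptor Nr4a1 by 5.26 ± 0.41, the platelet-derived growth factor receptor Pdgfrb by 3.98 ± 0.39 and the thymidylate synthase Tyms by 4.07 ± 0.23, while the mitotic kinase Aurkb fell by 3.62 ± 0.15. Hmox1 fell by 3.46 ± 0.32 and the thioredoxin reductase Txnrd1 rose by 2.08 ± 0.25, so NRF2 targets split 7 higher and 6 lower of 17.

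The lipid droplet list went both ways with LPS and compound, 4 higher and 4 lower of 14 with 25HC (median 0, adjusted p = 0.97), 4 and 6 with itraconazole (median -0.13, adjusted p = 0.81) and 4 and 8 with OSW-1 (median -0.94, adjusted p = 0.16). Dgat2, which makes triglyceride, rose by 3.17 ± 0.30 with itraconazole and LPS, and its LPS response differed by 2.66 ± 0.55 with 25HC, 3.55 ± 0.52 with itraconazole and 3.21 ± 0.51 with OSW-1. Hilpda, a lipase inhibitor, rose by 2.44 ± 0.30 with 25HC and LPS. Fabp5 was lower with each compound and LPS, at -2.40 ± 0.21, -2.58 ± 0.21 and -4.42 ± 0.23 for 25HC, itraconazole and OSW-1, and the cholesteryl ester hydrolase Nceh1 fell by 2.56 ± 0.11 with OSW-1 and LPS.

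OSW-1 with LPS differed from LPS alone at 9403 of 13173 tested genes. Different counting of the libraries is argued against: against Ch25h-/- cells with LPS, whose counts are odd and even like those of OSW-1, 8507 genes were called in the same direction. Damaged cells with more mitochondrial RNA are argued against by a median of -0.06 over the 13 mitochondrially encoded genes, 0 of which were higher and 4 lower by edgeR. Damage that leaves the share of mitochondrial RNA unchanged was not tested and stays open. A true and broad change of the cells remains a hypothesis that may hold. Whether the compound stayed on during LPS, and any vehicle, stay open.

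Interferon-stimulated genes were lower with each compound before LPS, and untreated wild-type cells that stand high in these genes could give that. Against unstimulated Ch25h-/- cells 19 of 34 members were lower with 25HC (median -0.75), 15 with itraconazole (-0.57) and 30 with OSW-1 (-1.72), with 0 higher by edgeR for each. The cut on the share of members called lower was set after the results were seen. By it, the result argues against high controls as the whole of the change for 25HC and OSW-1. Itraconazole, with 15 members lower against 19 for 25HC, missed that cut and is left undecided. The Ch25h-/- controls also differ from wild-type ones in genotype, animals and kind of counts, so the test changes these together. Untreated Ch25h-/- cells have a median of -0.68 against wild-type in these genes, with 0 of 34 called by edgeR (1717 of all tested genes at an unadjusted p under 0.05, 129 called by DESeq2 and 15 by limma-voom) and adjusted p = 0.5 with an estimated correlation. An effect of vehicle stays open.

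Removing wild-type mouse 3 raised the genes called between genotypes from 30 to 3679 with LPS and from 1 to 1787 unstimulated. Mouse 3 may be a mislabelled Ch25h-/- animal, but its untreated libraries held Ch25h at 1.16 CPM (0.828 to 1.59), against at most 0.25 in a Ch25h-/- animal. Removing mouse 1 or mouse 2 called at most 0 genes with LPS by edgeR, so among wild-type mice the effect with LPS is particular to mouse 3. No Ch25h-/- animal was left out with both its libraries. For the comparison with LPS, a weaker inflammatory response of this animal is a candidate explanation left undecided. Its inflammatory list median was lowest with LPS alone (4.18 against 5.27 and 4.91) and in 2 of the 3 compound groups with LPS. Of these, itraconazole gave 6.74 in mouse 3 against 8.8 and 8.58, but 25HC only 7.58 against 7.66 and 8.4. With OSW-1 and LPS mouse 3 was the highest (9.61 against 9.1 and 9.35). A weaker response to LPS does not cover the rise in unstimulated cells. There the list median of mouse 3 was the highest (-0.52 against -1.27 and -1.81). Mouse 3 also stood apart from mice 1 and 2 in every wild-type group, LPS-treated or not. Chi-square per degree of freedom between libraries, larger where they differ more, was 10.51 for untreated unstimulated mice 1 and 2. With mouse 3 it was 34.36 and 24.27. Which wild-type animals are typical stays open.

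The splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. In 14 of these comparisons 1 split, the real one, gave as many calls. Real and highest other counts were 8024 and 0 for the wild-type LPS response, 7534 and 1 for Ch25h-/-, 3784 and 68, 3533 and 0, and 4912 and 0 for unstimulated 25HC, itraconazole and OSW-1, and 5512 and 669, 7164 and 1097, and 9403 and 2 for the same compounds with LPS. They were 31 and 0, 373 and 0, and 834 and 0 between unstimulated compounds (25HC and itraconazole, 25HC and OSW-1, OSW-1 and itraconazole) and 861 and 529, 7738 and 0, and 6399 and 7 with LPS. Where mouse numbers pair the libraries, 3 other splits part all 3 pairs as the real one does, and these called 2 genes at most. Between genotypes, 2 of 10 splits unstimulated (1 and 186) and 3 of 10 with LPS (30 and 2280) gave as many. The split with 2280 sets wild-type mice 1 and 2 with Ch25h-/- mouse 3, which points to a structure of the samples.

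For differences of LPS response 25 splits, the real one included, were drawn within each LPS state, and chance is left open for all 4. Splits that keep the LPS libraries parted by compound hold the compound's effect with LPS. For itraconazole 4 of 25 splits gave as many genes as the real 3467 (5295 highest other), and for OSW-1 4 of 25 as many as the real 6808 (8088 highest other). The 3 others are in both cases splits of that kind, and the highest among the rest are 1961 and 1607. For 25HC 1 of 25, the real one, gave 1620 and the highest other 762, but 0 of the splits drawn were of that kind, so the draw itself sets this result. For the genotypes edgeR called 0 genes (1476 at an unadjusted p under 0.05, 8 by DESeq2, 1 by limma-voom), which all 25 of 25 splits reach by construction (highest other 145).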
